A study of Drosophila melanogaster with 9 samples.

How the data were processed

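Paired-end RNA sequencing was done on 9 libraries of pooled thoraces from female flies on adult day 20, with 3 libraries each for the groups 412KD, RooKD and scramble, as the sample titles name them. RNA was extracted with Trizol, per the labels' protocols. Reads were processed with HISAT2 and DESeq2 on build dm6, per the submitters' processing notes, without versions. The counting tool, the annotation release, the use of strand and the handling of reads with several matches are not given in the sources used here.

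The authors deposited 1 table per hairpin, each with the scramble libraries. Raw read counts per gene or repeat feature stand in the deposited tables, per the file headers, with 14166 features in the 412KD table and 14078 in the RooKD table and a total of at least 2 reads in each. The tables share 13765 features, with the same scramble counts in all of them, and 401 and 313 features stand in 1 table only. The deposited normalized signal is the read count divided by 1 size factor per library, as found from the values and estimated by the authors within each table. The deposited FPKM values are per kilobase and scaled to the library by the authors, per the file headers. The deposited log2 fold changes and the deposited p-values come from the authors' own comparison of each hairpin with scramble, per the file headers, and their adjusted p is written as 1 where no value was given. Only the counts entered the tests. The signal and FPKM values were read only to find how they had been made.

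Fits of all 9 libraries used the 13765 shared features. 6 low-complexity features of each table name no gene and were left out of library sizes and tests. They held 0.0019% to 0.2439% of the reads. 5 gene symbols that a spreadsheet had turned into dates were restored by their identifiers. Of 14299 FlyBase genes, 14203 were found in the reference annotation, 14116 with the same start and end. Coordinates are those of the authors' tables, on dm6, and 44 insertions of 412 and 144 of roo were taken from the reference annotation.

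Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr and the robust quasi-likelihood F test, at a Benjamini-Hochberg adjusted p of 0.05. Each comparison with scramble used its own 6 libraries, and 412KD against RooKD used all 9. Normalized counts are scaled by the TMM library sizes of the fit. DESeq2 1.42.0 was run as an alternative, and its missing adjusted p stayed missing. Gene lists for pathways and tissues, 40 in all, were fixed before the data were examined and tested with camera of limma 3.58.1, two-sided, with a preset correlation of 0.01 between genes and again with the correlation estimated from the data. The classes of repeat features were made after the tables had been seen. The targeted elements were tested by an exact permutation test of CPM, and the ratio of reads has a 95% Poisson interval. For a gene with no read in a group, the fold was taken against a floor of 3 reads in a library.

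On simulated counts with the fitted spread, edgeR recovered 43 of 100 genes changed by 1 log2 unit and 84 of 100 changed by 2 among 10431 genes for 412KD against scramble, with 16 false calls. For RooKD against scramble it recovered 57 and 86 of 100 among 10305 genes, with 8 false calls, and for 412KD against RooKD 36 and 83 of 100 among 10599 genes, with 9 false calls. DESeq2 recovered 61 and 88, 67 and 88, and 55 and 86 of 100, with 35, 20 and 44 false calls.

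The genes named were chosen by a rule written before the data were examined. In each comparison with scramble it takes the 12 genes up and the 12 down with the largest log2 fold change that pass the test, have a mean of at least 50 normalized counts and do not overlap between the groups. Up to 4 called members of a called list, the targeted elements and the transgene markers were added, and 5 genes each way for 412KD against RooKD. Because edgeR called only 2 genes in 412KD against scramble, the same rule was also applied, after seeing the data, to the calls of DESeq2 and to edgeR's calls without 412KD replicate 3 and RooKD replicate 1. Those fits give 105, 44 and 70 genes in the 3 comparisons, and DESeq2 gives 337, 346 and 81. For both comparisons with scramble, the fit without that library gives the highest of the 6 counts found by leaving out 1 library. PGRP-SC1a, PGRP-SC1b, CG11699 and slmo, which the rule leaves out for their counts, and Abl, unc-5, CG8160, HETA, TAHRE, TART_B1 in 412KD and fs(1)N in RooKD were chosen after their values had been seen. The marker gene y was too low to be tested.

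The alternatives were other normalizations, no filter on low counts, a minimum fold change, all 9 libraries or the 6 hairpin libraries alone, the replicate number as a block, each library left out in turn and, for the lists, the estimated correlation. DESeq2 without single libraries and edgeR without both libraries with high germline transcripts were added after seeing the data. So were library totals and a minimum fold change for 412KD against RooKD, library totals and other sets of libraries for the lists, and the overlap without both libraries. Each result was computed from the counts again under the alternatives that apply to it. The overlap of the hairpins was not run again with other normalizations, all 9 libraries or single hairpin libraries left out, nor the insertion tests beyond the distances and the estimated correlation. The replicate numbers do not pair the libraries by the test set beforehand, so the main fits have no block.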

Results

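RNA was sequenced, paired-end, from pooled thoraces of female Drosophila melanogaster on adult day 20, in a series whose title concerns retrotransposons and aging. The flies expressed a short hairpin RNA throughout the body under the promoter of the actin gene Act5C. One hairpin was directed against 412 and one against roo, both retrotransposons with long terminal repeats, and a scrambled hairpin was the control. Each group, labelled 412KD, RooKD or scramble, held 3 libraries. Reads per library ranged from 20600497 to 26177587 in 412KD, from 17590599 to 22361932 in RooKD and from 19766132 to 23545648 in scramble. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 22.3 to 175.4 over the 9 pairs, so each library was counted as a separate sample. The labels do not say whether the pools came from separate cultures, and the p-values measure only the spread between these pools, which can be technical.

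The libraries 412KD replicate 3 and RooKD replicate 1 stood apart from the rest. The leading principal component, with 40.2% of the variance, placed them at −61.5 and −49.5 and the other 7 libraries between −15.1 and 28.1. The median of the ovary and germline genes, as a log2 difference from the scramble mean, was 2.54 in 412KD replicate 3 against 0.19 and 0.13 in 412KD replicates 1 and 2. It was 2.54 in RooKD replicate 1 against −0.18 and 0.19 in RooKD replicates 2 and 3. These medians cover the members measured in each comparison with scramble. Over the 23 members measured across all 9 libraries, 412KD replicate 1 stood between, with a median of 0.48 and 11 members more than 1 log2 unit above the scramble mean, against 18 in 412KD replicate 3 and RooKD replicate 1, 4 in 412KD replicate 2 and 1 to 3 in the other libraries. The oocyte gene yl had 578, 12 and 4945 reads in 412KD, 2527, 0 and 0 in RooKD and 0 to 3 in scramble.

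Neither targeted element was lower in the libraries labelled as its knockdown. The 3 features of 412 held 51 reads in 412KD and 42 in scramble, or 0.699 ± 0.199 against 0.645 ± 0.160 CPM (SD, n = 3, exact permutation p = 0.8, two-sided, smallest possible 0.1). The ratio was 1.12, with a 95% counting interval of 0.730 to 1.73. The 2 features of roo held 664 reads in RooKD and 680 in scramble, or 11.2 ± 2.31 against 10.3 ± 2.40 CPM (SD, n = 3, exact permutation p = 0.7, two-sided), a ratio of 1.07 (0.961 to 1.19). By library, 412 was at 0.486, 0.879 and 0.733 CPM in 412KD, at 0.637, 0.810 and 0.489 CPM in scramble and at 0.447, 0.348 and 0.399 CPM in RooKD. Roo was at 11, 8.95 and 13.6 CPM in RooKD, at 12.9, 9.66 and 8.22 CPM in scramble and at 9.86, 11.8 and 8.72 CPM in 412KD. The internal part of 412, DM412, had a log2 fold change of −0.03 ± 0.41 (SE) in 412KD (edgeR adjusted p = 0.981), and the authors' deposited table gives −0.03 (adjusted p = 0.994). The internal part of roo, ROO_I, had 0.26 ± 0.24 in RooKD (edgeR adjusted p = 0.670), and the authors' deposited table gives 0.26 (adjusted p = 0.772). The intervals cover counting error only, and how reads matching several copies of an element were counted is not given in the sources used here. The RNA levels thus do not show the falls that the labels name, and with 51 and 42 reads a fall of 412 is not excluded. Every direction given here is drawn between the libraries labelled 412KD, RooKD and scramble. Across the hairpins, 412 stood at a ratio of 0.627 (0.363 to 1.06) in RooKD against scramble (exact permutation p = 0.1), and roo at 0.984 (0.885 to 1.09) in 412KD against scramble (exact permutation p = 1).

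**Figure D1:**
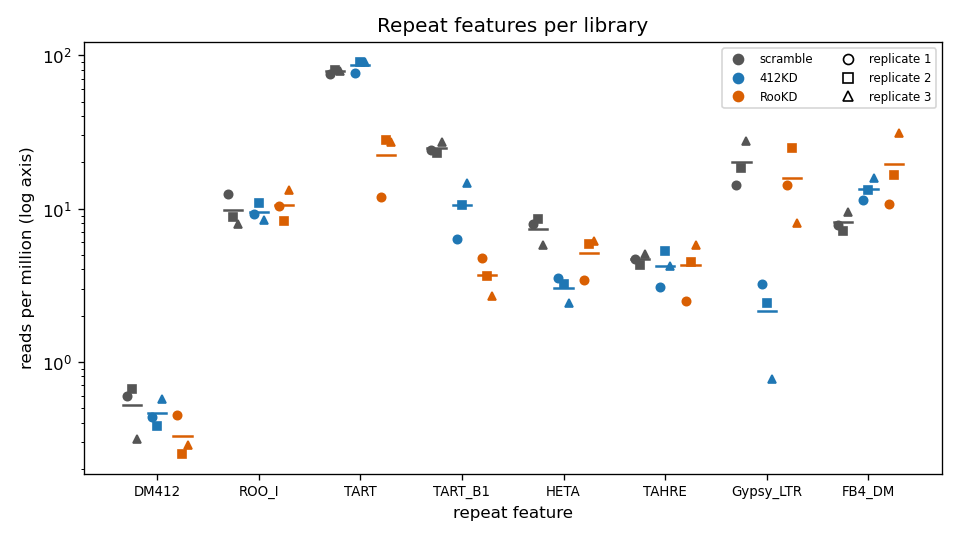
CPM (log axis) of 8 repeat features in each of the 9 libraries; points are libraries, their shape gives the replicate, and short lines are group means of 3. DM412 and ROO_I overlap between the groups, while TART_B1 lies at 2.68 to 4.74 CPM in the libraries labelled RooKD against 23.2 to 27.1 CPM in scramble.

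The comparison of 412KD with scramble asks which thoracic transcripts differ in flies given the 412 hairpin. In the libraries labelled 412KD, PGRP-SC1a, which encodes an amidase that breaks down peptidoglycan (2R, 8709733 to 8710320), rose from 3.60 ± 1.28 to 94.7 ± 8.61 normalized counts (SD, n = 3), a log2 fold change of 4.66 ± 0.33 (SE, edgeR adjusted p = 0.0202). The pseudogene CR18217 (3L, 16600448 to 16602723) rose from 158 ± 2.73 to 929 ± 229 normalized counts, a log2 fold change of 2.56 ± 0.19 (edgeR adjusted p = 0.0202). By camera with a preset correlation, digestive enzyme genes and the protein-coding genes of the mitochondrial genome were called upward and hemocyte genes downward. With an estimated correlation all 3 lists had an adjusted p of 0.903, and without 412KD replicate 3 the hemocyte list was not called (adjusted p = 0.0827). PGRP-SC1a has a near-identical copy, PGRP-SC1b (1.39 ± 0.49, edgeR adjusted p = 0.395), so its value is uncertain. With 1 library left out in turn, the edgeR adjusted p ranged from 0.00377 to 0.126 for PGRP-SC1a, which passed without 412KD replicate 3 alone, and from 0.00141 to 0.136 for CR18217, which passed without 412KD replicate 2 or 3. The promoter gene Act5C and the eye colour genes v and w, markers used in fly transgenes, had log2 fold changes of −0.27 ± 0.13, 0.46 ± 0.20 and −0.12 ± 0.09 (edgeR adjusted p = 0.504, 0.459 and 0.644).

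Of 40 digestive enzyme genes measured, 38 had a log2 fold change above 0 in the libraries labelled 412KD, with a median of 1.35 (camera adjusted p = 1.99e-16 with a preset correlation, p = 0.0321 and adjusted p = 0.903 with an estimated correlation). The library medians were 1.90, 0.89 and 1.43 above the scramble mean, and without 412KD replicate 3 the list kept its direction (camera adjusted p = 6.70e-14). edgeR called 0 members over all genes and 22 up and 1 down adjusted over the list alone, and DESeq2 called 18 up over all genes. The protease genes Jon25Bii (3260 ± 157 against 559 ± 223 normalized counts, SD, n = 3) and Jon99Ci (1461 ± 429 against 98.5 ± 75.3) had log2 fold changes of 2.54 ± 0.30 and 3.88 ± 0.56 and passed DESeq2 (adjusted p = 3.82e-15 and 1.78e-14) but not edgeR (adjusted p = 0.0796 and 0.0956). Jon genes have near-identical copies, so their single values are uncertain.

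All 13 mitochondrially encoded genes had log2 fold changes above 0 in 412KD, with a median of 0.96 (camera adjusted p = 1.31e-10, p = 0.0696 and adjusted p = 0.903 with an estimated correlation). edgeR called 0 over all genes and 10 up adjusted over the list alone, and DESeq2 called 7 up over all genes. mt:CoII, a subunit of cytochrome c oxidase, and mt:ATPase6, a subunit of ATP synthase, had log2 fold changes of 1.24 ± 0.23 and 0.96 ± 0.18 and passed DESeq2 (adjusted p = 5.26e-05 and 0.000228) but not edgeR (adjusted p = 0.144 and 0.145). Of the hemocyte genes 15 of 21 were below 0, with a median of −0.35 (camera adjusted p = 0.00659, p = 0.238 with an estimated correlation). By library medians of this list, 412KD replicate 1 (−0.18) lay above scramble replicate 2 (−0.212). Among the hemocyte genes NimC1, a phagocytosis receptor gene, had a log2 fold change of −0.96 ± 0.25 (DESeq2 adjusted p = 0.0120, edgeR adjusted p = 0.270).

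Camera with the preset correlation called 10 further lists in 412KD. Upward were nuclear genes of oxidative phosphorylation (58 of 65 above 0, median 0.15, adjusted p = 0.00165), the citric acid cycle (19 of 23, 0.26, adjusted p = 0.00659), flight muscle sarcomere genes (31 of 41, 0.16, adjusted p = 0.00659), ovary and germline genes (13 of 16, 1.47, adjusted p = 0.00659) and glycolysis genes (15 of 19, 0.16, adjusted p = 0.0143). Neuromuscular genes (22 of 26, 0.15, adjusted p = 0.0143), piRNA pathway genes (27 of 32, 0.26, adjusted p = 0.0172) and ribosomal protein genes (57 of 82, 0.07, adjusted p = 0.0289) were also called upward. Downward were apoptosis genes (17 of 23 below 0, median −0.12, adjusted p = 0.0395) and heat shock genes (18 of 23, −0.20, adjusted p = 0.0402). With an estimated correlation all of these had an adjusted p of 0.903. In each of the 10 lists the library medians overlapped between 412KD and scramble. For oxidative phosphorylation 412KD replicate 2 (−0.149) lay below all scramble libraries (−0.113 or more). For the citric acid cycle that library (−0.076) also lay below all scramble libraries (−0.036 or more). Without 412KD replicate 3, the library with high germline transcripts, camera no longer called the lists of oxidative phosphorylation (adjusted p = 0.378), the citric acid cycle (0.212), ovary and germline (0.251), piRNA pathway (0.993), apoptosis (0.378) and hemocyte genes (0.0827). Antimicrobial peptide genes, with library medians of 0.25, 0.60 and −1.70, were called upward without that library (camera adjusted p = 0.0215, against 0.630 with all libraries). So were the lists of immune regulators (2.36e-06), immune peptidases (0.000148), proteasome (0.00457), cytochrome P450 (0.0128) and lipid metabolism (0.0387). Other splits of the same 6 libraries called up to 18 lists, against 13 here.

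DESeq2 called 214 genes up and 123 down in 412KD. Some of its largest rises rested to a great part on 412KD replicate 3, such as yl, the yolk protein receptor gene of the oocyte (normalized counts of 701, 10.9 and 4626 in the 3 libraries), and dhd, a germline thioredoxin gene (369, 22.7 and 4807). Other large rises did not, since the edgeR log2 fold changes of CG8664 and CG3117 were 8.88 and 5.66 with all libraries and 9.39 and 6.05 without that library. Down by DESeq2 were lncRNA:CR45662 (−5.81 ± 0.79, edgeR), Gr43a, a fructose receptor gene (−4.07 ± 0.66), Hr51, a nuclear receptor gene (−3.33 ± 0.47), PH4alphaSG2, a prolyl hydroxylase gene (−3.13 ± 0.50), the LTR feature Gypsy_LTR (−3.11 ± 0.55), Drsl5, a drosomycin-like gene (−2.42 ± 0.45), and Lsp1beta, a larval storage protein gene (−2.31 ± 0.53). Their edgeR adjusted p were 0.0832 (lncRNA:CR45662), 0.124 (Gr43a), 0.0832 (Hr51), 0.115 (PH4alphaSG2), 0.138 (Gypsy_LTR), 0.152 (Drsl5) and 0.233 (Lsp1beta). Without 412KD replicate 3 edgeR called 88 genes up and 17 down, the 2 of all libraries among them. These included the antibacterial peptide gene AttA (3.25 ± 0.28), the BMP receptor gene wit (2.52 ± 0.17), the centrosome gene spd-2 (2.57 ± 0.24), the kinase gene Abl (1.85 ± 0.11) and CG3117 (6.05 ± 0.37). The glutathione transferase gene GstE1 (−1.76 ± 0.16) and the cytochrome P450 gene Cyp6g2 (−1.49 ± 0.10) were among those lower. Of 76 repeat features tested in 412KD, edgeR called 0 and DESeq2 called 4 up and 3 down.

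By edgeR, 1168 of 10431 genes had an unadjusted p under 0.05 in 412KD against scramble. The libraries of the 2 groups did not overlap in 17.7% of the genes, where chance gives 10% on average over all splits. Genes vary together and the share was not computed for the other splits, so an excess is not shown. edgeR's count of 2 went to 105 without 412KD replicate 3, to 1 without 412KD replicate 2, and to 0 without 412KD replicate 1, scramble replicate 1 or scramble replicate 2, where DESeq2 with all libraries called 337.

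**Figure D2:**
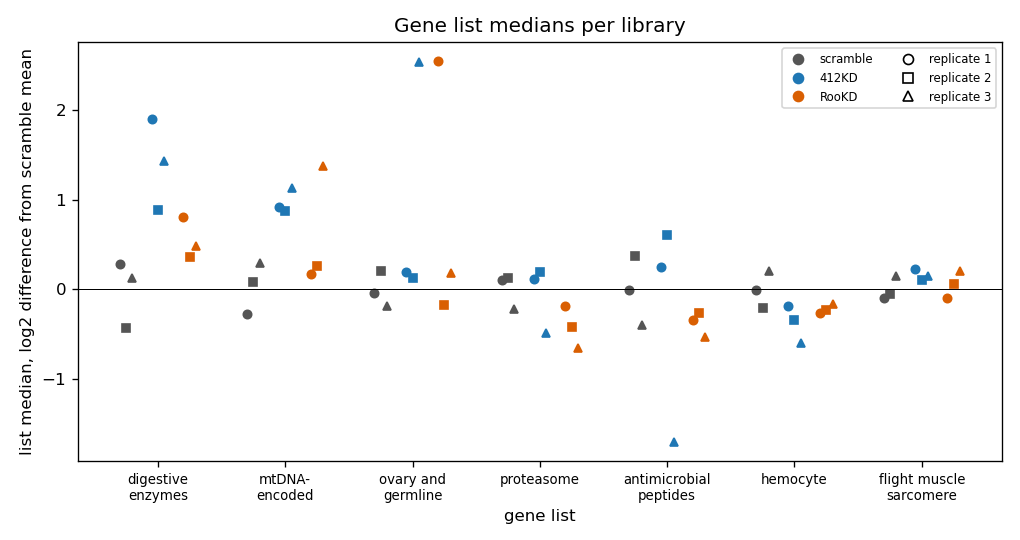
Medians of 7 gene lists in each of the 9 libraries, as log2 differences from the scramble mean; points are libraries and their shape gives the replicate. The digestive enzyme medians of the libraries labelled 412KD lie at 0.89 to 1.90, and the ovary and germline medians of 412KD replicate 3 and RooKD replicate 1 stand at 2.54.

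The comparison of RooKD with scramble asks which thoracic transcripts differ in flies given the roo hairpin. In the libraries labelled RooKD, edgeR called 4 genes up and 7 down. Reepl1 (X, 11572707 to 11573640) had 0 reads in all 3 libraries labelled RooKD and 149 to 213 in scramble, at least 46.9-fold lower against a floor of 3 reads in the shallowest RooKD library (edgeR adjusted p = 0.00513). Its neighbour Kmn1, a kinetochore gene (X, 11571383 to 11572442), fell by 2.19 on the log2 scale (SE 0.27, edgeR adjusted p = 0.0427), and TART_B1, a feature of the telomeric retrotransposon TART, fell from 501 ± 65.2 to 80.7 ± 20.5 normalized counts (SD, n = 3), a log2 fold change of −2.63 ± 0.22 (edgeR adjusted p = 0.00603). Up were Ork1, a potassium leak channel gene (1.47 ± 0.13, edgeR adjusted p = 0.00886), Gba1b, a glucocerebrosidase gene (1.14 ± 0.13, 0.0306), Ldsdh1, a lipid droplet dehydrogenase gene (1.15 ± 0.13, 0.0306), and CG14823 (1.52 ± 0.16, 0.0262).

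Also down in RooKD by edgeR were PH4alphaSG2 (−3.94 ± 0.29, adjusted p = 0.00513), Hr51 (−3.69 ± 0.43, adjusted p = 0.0333), CG14431 (−1.39 ± 0.17, adjusted p = 0.0427) and CG42846 (−1.37 ± 0.12, adjusted p = 0.00603). Kmn1 overlaps CG11699 on the other strand, so reads in their overlap may be counted for either gene and both values are uncertain to that extent. TART and TART_B1 can share reads too. TART itself had −1.68 ± 0.32 in RooKD (edgeR adjusted p = 0.134, with 0.0143 to 0.506 over the libraries left out in turn, and DESeq2 adjusted p = 8.35e-06). Of 73 repeat features tested in RooKD, edgeR called TART_B1 alone, and DESeq2 called 1 up and 2 down. The marker genes Act5C, v and w had log2 fold changes of 0.05 ± 0.16, 1.13 ± 0.20 and −0.23 ± 0.15 (edgeR adjusted p = 0.927, 0.0989 and 0.553). Of these v passed DESeq2 (adjusted p = 9.49e-05), with no overlap between the libraries of the 2 groups.

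All 32 proteasome genes had log2 fold changes below 0 in the libraries labelled RooKD, with a median of −0.41 (camera adjusted p = 1.11e-11, p = 0.166 and adjusted p = 0.783 with an estimated correlation). The library medians were −0.18, −0.42 and −0.66, and scramble replicate 3 stood at −0.21. edgeR called 0 members over all genes and 0 adjusted over the list alone. DESeq2 called 2 down over all genes, Prosalpha4 (−0.69 ± 0.18 in edgeR) and Rpt3 (−0.50 ± 0.14 in edgeR), and 14 down adjusted over the list alone.

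Lipid metabolism genes rose as a group in RooKD, with 20 of 29 above 0 and a median of 0.27 (camera adjusted p = 0.00921, p = 0.0962 with an estimated correlation). The fatty acid synthase gene FASN1 (0.94 ± 0.16) and the desaturase gene Desat1 (0.94 ± 0.18) passed DESeq2 (adjusted p = 1.53e-07 and 1.21e-05) but not edgeR (adjusted p = 0.0954 and 0.122). Cytochrome P450 genes (32 of 47 above 0, median 0.23), neuromuscular genes (24 of 26, 0.17), digestive enzyme genes (33 of 38, 0.72) and mitochondrially encoded genes (13 of 13, 0.65) also rose as groups, each with a camera adjusted p of 0.00518. With an estimated correlation these 4 lists had p = 0.133, 0.406, 0.149 and 0.259. The mitochondrial medians by library were 0.17, 0.26 and 1.38, and scramble replicate 3 stood at 0.30, above RooKD replicates 1 and 2. For neuromuscular genes RooKD replicate 1 (−0.034) lay below scramble replicate 2 (0.125). For lipid metabolism genes RooKD replicate 1 (0.121) lay below scramble replicate 3 (0.144). The medians of the digestive and cytochrome P450 lists did not overlap between RooKD and scramble. Antimicrobial peptide genes fell as a group, with 23 of 31 below 0 and a median of −0.30 (camera adjusted p = 0.0141, p = 0.210 with an estimated correlation), and DptB, a diptericin gene, had −0.92 ± 0.19 (DESeq2 adjusted p = 0.000416, edgeR adjusted p = 0.135). The antimicrobial medians by library were −0.342, −0.258 and −0.531, and scramble replicate 3 stood at −0.385, below RooKD replicates 1 and 2. Hemocyte genes (16 of 21 below 0, median −0.32, adjusted p = 0.0305), heat shock genes (14 of 22, −0.17, adjusted p = 0.0461) and apoptosis genes (17 of 23, −0.11, adjusted p = 0.0461) fell as groups by camera, with p = 0.252, 0.165 and 0.120 with an estimated correlation. All adjusted p of these lists were 0.783 with an estimated correlation. The library medians of the hemocyte, heat shock and apoptosis lists also overlapped between RooKD and scramble. Without RooKD replicate 1, the library with high germline transcripts, camera no longer called the antimicrobial peptide (adjusted p = 0.0812), cytochrome P450 (0.110), hemocyte (0.194) and apoptosis lists (0.194). It then called DNA damage genes (0.00114, against 0.246 with all libraries) and piRNA pathway genes (0.0202, against 0.742) downward. Other splits of the same 6 libraries called up to 13 lists, against 10 here.

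DESeq2 called 235 genes up and 111 down in RooKD, and edgeR gave an unadjusted p under 0.05 to 1306 of 10305 genes. Low by DESeq2 were MCO3, a multicopper oxidase gene (2, 0 and 0 reads against 208, 104 and 36 in scramble), Gr43a (−6.09 ± 0.75, edgeR) and Cyp4p2, a cytochrome P450 gene (−3.08 ± 0.54), and high was the peptidase gene CG8773 (3.16 ± 0.44). The libraries of the 2 groups did not overlap in 18.7% of the genes, where chance gives 10% on average over all splits. The share was not computed for the other splits here either, so an excess is not shown. edgeR's count of 11 went to 44 without RooKD replicate 1, all 11 among them, and to 18 without scramble replicate 3. It went to 7 without RooKD replicate 3, to 4 without scramble replicate 1 and to 0 without scramble replicate 2, where DESeq2 with all libraries called 346.

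**Figure D3:**
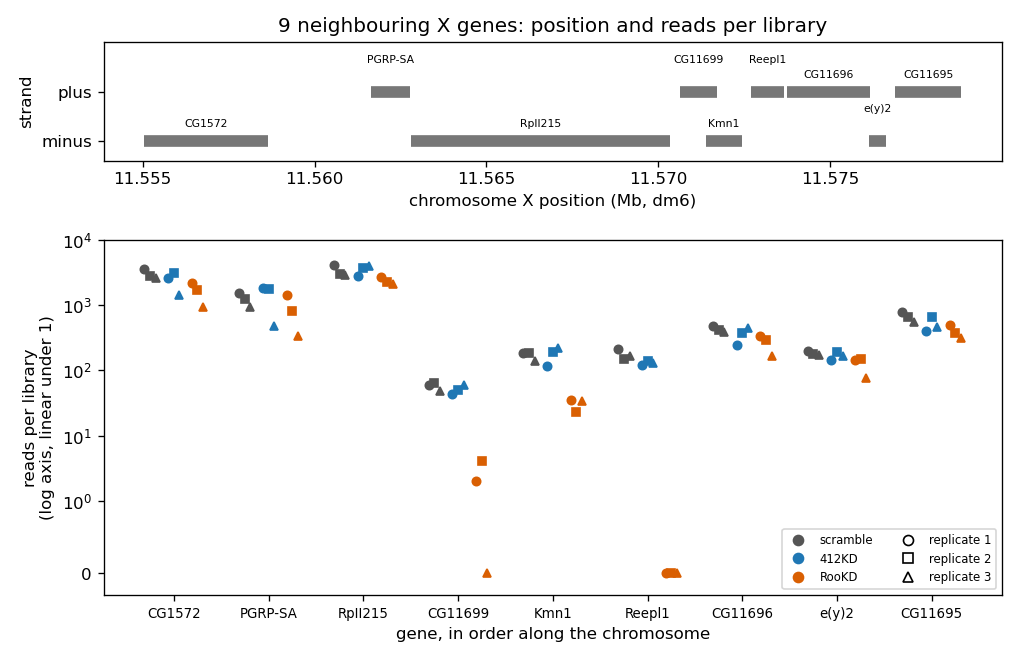
Positions of 9 neighbouring genes on chromosome X by strand (upper panel, Mb, dm6) and their reads per library in the same order (lower panel, log axis, linear under 1); points are the 9 libraries and their shape gives the replicate. Reepl1 has 0 reads in all 3 libraries labelled RooKD, CG11699 has 0 to 4 and Kmn1 has 23 to 35, while the 3 genes on either side keep 76 reads or more.

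The direct comparison of 412KD with RooKD asks which transcripts differ between the hairpins, with the shared control cancelled. edgeR called 6 genes higher in the libraries labelled 412KD than in those labelled RooKD and 4 lower. Higher were 3 neighbours on X, Reepl1 (0 reads in RooKD, adjusted p = 0.000364), CG11699 (4.37 ± 0.59, adjusted p = 0.0479) and Kmn1 (2.24 ± 0.26, adjusted p = 0.0226), the pseudogene CR18217 (2.57 ± 0.18, adjusted p = 0.000667), CG3117 (7.94 ± 1.01, adjusted p = 0.0479) and slmo, a gene of mitochondrial lipid transfer (2.90 ± 0.40, adjusted p = 0.0479). Lower were CG11893 (−3.07 ± 0.34, adjusted p = 0.0226), CG12934 (−2.83 ± 0.35, adjusted p = 0.0479), the cytochrome P450 gene Cyp4p1 (−1.86 ± 0.26, adjusted p = 0.0479) and lectin-24Db, a C-type lectin gene (−1.42 ± 0.18, adjusted p = 0.0365). PGRP-SC1a, up in 412KD against scramble, stood at 207, 1.12 and 1.30 normalized counts in the 3 libraries labelled RooKD, and its difference between the hairpins did not pass (0.35, edgeR adjusted p = 0.997). It passed without RooKD replicate 1 (6.08, edgeR adjusted p = 0.00373) and turned to −0.23 and −0.22 without RooKD replicate 2 or 3.

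Between the hairpins, all 32 proteasome genes were higher in the libraries labelled 412KD (median 0.41, camera adjusted p = 1.03e-09), as were 33 of 41 digestive enzyme genes (0.71, adjusted p = 1.89e-09) and 13 of 13 mitochondrially encoded genes (0.32, adjusted p = 0.00753). Cytochrome P450 genes were lower, with 32 of 47 below 0 (median −0.12, camera adjusted p = 0.0369). By library medians, as log2 differences from the RooKD mean, the groups were apart only in the digestive list (0.75 or more in 412KD, 0.47 or less in RooKD). For the proteasome 412KD replicate 3 (−0.05) lay below RooKD replicate 1 (0.25), for the mitochondrial list RooKD replicate 3 (0.73) lay above all 412KD libraries (0.65 or less), and for cytochrome P450 genes 412KD replicate 1 (0.06) lay above RooKD replicate 2 (−0.07). With an estimated correlation the 4 lists had p = 0.203, 0.0205, 0.236 and 0.291 and adjusted p = 0.913, 0.712, 0.913 and 0.913. Without 412KD replicate 3 and RooKD replicate 1 the mitochondrial list was no longer called (camera adjusted p = 0.812) and the cytochrome P450 list turned upward (0.438). Immune regulators (1.32e-07), antimicrobial peptides (4.51e-05), immune peptidases (0.00280) and DNA damage genes (0.0190) were then called upward and neuromuscular genes (0.0119) downward. Other splits of the 6 libraries called up to 18 lists, against 4 here.

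edgeR gave an unadjusted p under 0.05 to 638 of 10599 genes between 412KD and RooKD, and DESeq2 called 47 up and 34 down. The libraries of the 2 groups did not overlap in 9.1% of the genes, where chance gives 10% on average over all splits. edgeR's count of 10 went to 70 without both libraries with high germline transcripts, 9 of the 10 among them, and to 22 without 412KD replicate 3 alone. It went to 4 without 412KD replicate 1 and to 2 without 412KD replicate 2, RooKD replicate 2 or RooKD replicate 3.

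Whether both hairpins moved the same genes was asked from the calls and from the fold changes. edgeR called no gene in both comparisons with scramble, with 1168 and 1306 genes at an unadjusted p under 0.05, while DESeq2 called 66 genes up in both, 32 down in both and 1, CG12934, down in 412KD and up in RooKD. Among those down in both were lncRNA:CR45662, MCO3, Gr43a, Hr51, PH4alphaSG2 and Drsl5, and among those up in both were CG8773 and fs(1)N, a gene of the eggshell. fs(1)N had 104, 26 and 265 reads in 412KD and 253, 6 and 19 in RooKD against 3 to 7 in scramble. Among the 10127 features with a DESeq2 adjusted p in both comparisons, 162 were called up and 121 down in 412KD, and 234 and 111 in RooKD. Independent lists of these sizes would share 3.74 up and 1.33 down, and 5 simulations without any effect, against the same controls, gave 3.2 shared calls on average and 6 at most. Across 10256 genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.713 against 0.502 on average in 20 simulations without an effect, and a Spearman correlation of 0.636 against 0.466. The covariance was 0.192 against 0.074 simulated, a difference of 0.118. The independent lists leave out the shared controls and the simulations leave out real effects. All simulations given here also drew each gene independently. Genes that vary together between libraries can make these measures and the shared calls vary more than simulated. The simulated values are therefore no bound on what arises without an effect. Part of the excess of shared calls over independent lists may come from the shared controls, which are too few to be split into parts of 2 libraries. A difference of the scramble flies from both hairpin groups would also give shared calls, and the simulations hold no such difference. The labels do not separate hairpin and fly line, so shared calls do not show a shared effect of the hairpins. Each comparison also holds 1 library with high germline transcripts. In a test added after seeing the data, without 412KD replicate 3 and RooKD replicate 1, the Pearson correlation was 0.33 across 10370 genes, against 0.393 on average in 20 simulations without an effect. The covariance was 0.095 against 0.081 simulated (0.104 at most). These simulations took their spread from all 9 libraries, the 2 left out included, so they may overstate the covariance. Without the 2 libraries the correlation thus showed no excess over the simulations, which does not exclude a shared part. For the covariance it is not decided whether an excess remains. edgeR then called 8 genes in the same direction in both comparisons, PH4alphaSG2 among them, and 1 in opposite directions, against 0.1 shared calls on average in the 20 simulations and 1 at most. DESeq2 called 129 in the same direction and 8 in opposite directions, against 5.6 on average in 5 simulations and 7 at most, and independent lists would share 7.97 up and 2.98 down. Of the 98 genes that DESeq2 called in the same direction with all libraries, 68 were among these 129, and fs(1)N was not.

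Genes beside reference insertions of the targeted elements were compared with all other genes. The 36 genes that hold or lie within 2 kb of a 412 insertion had a median log2 fold change of 0.10 in 412KD (camera two-sided p = 0.239 with the preset correlation). Within 10 kb of a 412 insertion there were 100 genes, with a median of 0.04 (camera two-sided p = 0.4995 with the preset correlation). The 111 genes beside a roo insertion had a median of 0.12 in RooKD, with 73 above 0 (camera two-sided p = 0.0351, and p = 0.340 with an estimated correlation). The 83 genes that hold a roo insertion inside their span had a median of 0.05 (camera two-sided p = 0.231 with the preset correlation). The 217 genes within 10 kb had a median of 0.11 (camera two-sided p = 0.0184, and p = 0.191 with an estimated correlation). In 412KD, whose hairpin was not directed at roo, the 110 genes beside a roo insertion had a median of 0.08 (camera two-sided p = 0.0173, and p = 0.177 with an estimated correlation). In RooKD, whose hairpin was not directed at 412, the 21 genes that hold a 412 insertion had a median of 0.14 (camera two-sided p = 0.0463, and p = 0.0945 with an estimated correlation), against 0.09 in 412KD (camera two-sided p = 0.215 with the preset correlation). The 36 genes within 2 kb of a 412 insertion had a median of 0.12 in RooKD (camera two-sided p = 0.167 with the preset correlation).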

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

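The tests of a hairpin effect on germline genes, of midgut tissue, of Jon, Try and Lys copies, of abdominal carry-over and of shared reads on X were chosen after the result was seen. The tests of ovarian tissue, of library depth, of a local difference on X and of other splits were written before.

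The direct test between the hairpins singled out 10 genes and 4 lists, as differences between the libraries labelled 412KD and RooKD, whose flies may differ in line as well as in hairpin. In the libraries labelled 412KD against those labelled RooKD, the fitted log2 differences were 9.96 for Reepl1 (0 reads in RooKD, so no bound), 7.94 for CG3117, 4.37 for CG11699, 2.9 for slmo, 2.57 for CR18217 and 2.24 for Kmn1. They were −3.07 for CG11893, −2.83 for CG12934, −1.86 for Cyp4p1 and −1.42 for lectin-24Db. The list medians were 0.71 for digestive enzyme genes, 0.41 for proteasome genes, 0.32 for mitochondrially encoded genes and −0.12 for cytochrome P450 genes. With an estimated correlation their camera adjusted p were 0.712 for digestive enzyme genes and 0.913 for the others. The mitochondrial list was not called without 412KD replicate 3 and RooKD replicate 1 (0.812), and the cytochrome P450 list then turned upward (0.4377). Low-complexity AT-rich reads, which no comparison used, were above the highest scramble library (807) with 2218, 5799 and 6501 reads in the 3 libraries labelled 412KD and with 871 and 42644 reads in RooKD replicates 2 and 3.

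Germline genes were high in 412KD replicate 3 and RooKD replicate 1. A second list of 18 germline genes, 17 of them measured and none shared with the first lists, had medians of 2.82 and 2.422 log2 units above the other 2 libraries of the same group, with 16 and 17 members higher, as ovarian tissue in these thorax pools would bring. Against the scramble mean the 4 other hairpin libraries were at most 0.328, in 412KD replicate 1, where 11 of 23 members of the first list were more than 1 log2 unit higher, and at −0.009, −0.151 and −0.128 in 412KD replicate 2 and RooKD replicates 2 and 3, which argues against an effect shared by all libraries of a hairpin. Both libraries stood at percentile 100 among 10000 random lists matched on expression, which argues against depth or composition. Ovarian tissue stays open as a hypothesis, and whether these pools held it was not tested otherwise.

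Digestive enzyme genes were high in the libraries labelled 412KD. The lower median of 412KD replicates 1 and 2 was 0.89, in replicate 2. There 4 of 23 ovary and germline genes were more than 1 log2 unit above scramble. This argues against carry-over of abdominal tissue with ovaries as the whole cause. The median was higher in 412KD replicates 1 and 3 (1.90 and 1.43), and in RooKD it was highest in replicate 1 (0.81 against 0.36 and 0.48). A part from such carry-over is thus not excluded, and carry-over of gut without ovaries was not tested. The 11 members outside the Jon, Try and Lys families had a median of 0.824, all 11 above 0. This argues against reads shared within these families as the whole cause. Reads shared between other copies, such as Amy-p (0.824) and Amy-d (0.641) within this set, were not tested. A larger share of midgut tissue was taken to raise its genes alike, which was not itself tested. The 10 most abundant members differed by more than their errors (chi-square heterogeneity p = 9.945e-13), as did all tested members (p = 7.613e-52). Without LysP (−0.42), a set tried only after that result, the others gave a heterogeneity p of 0.343, so the test of the 10 rests on LysP, while the 34 members without Lys genes still differed (2.25e-32). The chi-square test takes the errors as known and the genes, measured in the same 6 libraries, as independent. It therefore does not decide about midgut tissue, which stays open. An effect of the 412 hairpin on these genes also stays open and was not tested, since the labels do not separate hairpin and fly line.

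Reepl1, CG11699 and Kmn1, neighbours on X, were near 0 or low in the libraries labelled RooKD. The 3 tested genes on either side had a median log2 fold change of −0.407, within the 0.5 set before this test for a deletion or other local difference in the RooKD flies. All of them were below 0, from −0.669 (CG1572) to −0.242 (RpII215), and CG11695 (−0.514) also lay beyond 0.5. None passed edgeR (adjusted p = 0.217 to 0.767). Reepl1 overlaps neither of the others and had a fitted log2 fold change of −10.335 (no bound, since RooKD has 0 reads), which argues against reads shared between overlapping genes. A local difference stays open as a hypothesis, as does an effect of the roo hairpin, which was not tested.

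Each group of 6 libraries has only 10 splits into 3 and 3, too few for a share under 0.05. In 412KD against scramble the real split called 2 genes and the highest other 0, with 1 split, the real one, giving as many. For lists the values were 13 and 18, with 9 splits giving as many. In RooKD against scramble they were 11 and 5 genes (1 split) and 10 and 13 lists (3 splits). In 412KD against RooKD they were 10 and 16 genes (2 splits) and 4 and 18 lists (10 splits). The split with 16 genes puts 412KD replicate 3 and RooKD replicate 1, the libraries with high germline transcripts, on the same side. A split that calls 18 lists where the real one calls 4 shows that many lists can be called with the preset correlation when the groups are mixed. The cause was not tested.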

How the results depend on the processing

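DESeq2 without single libraries, edgeR without both libraries with high germline transcripts, library totals and a minimum log2 fold change of 1 for 412KD against RooKD, the overlap without both of these libraries and, for the lists, library totals and other sets of libraries were tests chosen after the result was seen.

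In 412KD against scramble, edgeR called 2 genes. It called 14 with library totals only (7 up and 7 down), 15 with no filter on low counts and 14 with all 9 libraries, and DESeq2 called 337, or 526 without 412KD replicate 3. In RooKD against scramble edgeR called 11 genes and 26 with no filter, and DESeq2 called 346, or 467 without RooKD replicate 1. In 412KD against RooKD edgeR called 10 genes, 4 with the 6 knockdown libraries alone and 70 without 412KD replicate 3 and RooKD replicate 1. DESeq2 called 81, or 210 without 412KD replicate 3 and 188 without RooKD replicate 1. The cause of these shifts was not tested.

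With 1 library left out in turn, the genes called by edgeR ranged from 0 to 105 in 412KD against scramble (105 without 412KD replicate 3), from 0 to 44 in RooKD against scramble (44 without RooKD replicate 1) and from 2 to 22 in 412KD against RooKD. The lists called by camera ranged from 6 to 15, from 8 to 12 and from 5 to 13.

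With an estimated correlation camera called 0, 0 and 0 lists at an adjusted p of 0.05 in the 3 comparisons, with 1, 0 and 2 at an unadjusted p under 0.05, against 13, 10 and 4 with the preset correlation. With all 9 libraries 6 lists were called in RooKD against scramble. Without 412KD replicate 3 and RooKD replicate 1, 7 lists were called in 412KD against RooKD, and the cytochrome P450 list turned upward (camera adjusted p = 0.4377, with 0.000317 to 0.994 over its alternatives).

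The replicate block gave 0 genes in 412KD against scramble (edgeR, with 1168 at an unadjusted p under 0.05 without the block and 337 by DESeq2), 10 in RooKD against scramble and 4 in 412KD against RooKD, with 14, 9 and 5 lists. Libraries of the same number had residual correlations of 0.0966, 0.134 and 0.133 between 412KD and scramble, 0.24, −0.0521 and 0.0557 between RooKD and scramble and 0.00148, 0.393 and −0.21 between 412KD and RooKD, so pairing was not shown by the test set beforehand. As a hint from the data, every library of 412KD and scramble correlates best with its own number in that comparison, which is not so in the other 2 comparisons.

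DM412 in 412KD ranged from −0.272 to 0.137 over the libraries left out, above 0 at 0.093, 0.067 and 0.137 without 412KD replicate 2, scramble replicate 1 or scramble replicate 2. ROO_I in RooKD ranged from 0.051 to 0.45. Act5C in RooKD (0.05) went to −0.088 with library totals only and ranged from −0.026 to 0.118, below 0 also at −0.009. TAHRE in RooKD (−0.01) ranged from −0.304 to 0.265, above 0 also at 0.096, and DESeq2 without RooKD replicate 1 gave 0.273. PGRP-SC1a in 412KD against RooKD ranged from −0.227 to 6.081, below 0 also at −0.22.

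Genes called in both comparisons with scramble numbered 0 by edgeR (0 to 0 without single scramble libraries), 1 with no filter and 98 by DESeq2. Without 412KD replicate 3 and RooKD replicate 1 they numbered 8 by edgeR and 129 by DESeq2. The correlation of the log2 fold changes was 0.743 to 0.774 without single scramble libraries and 0.33 without 412KD replicate 3 and RooKD replicate 1. Genes that hold a roo insertion inside their span had a median of 0.045 in RooKD, and with an estimated correlation the genes beside a roo insertion had p = 0.3396, both no longer past 0.05, while the genes within 10 kb (median 0.107) stayed past it with the preset correlation (camera p = 0.01843) but not with an estimated one (p = 0.1907).

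Of the other values of single genes and lists under an alternative, 1036 kept direction and side of the threshold, 207 kept direction and no longer passed, and 133 kept direction and came to pass. Another 12 changed direction. Among the main values of the comparisons, 78 stayed within 1.5 times their value or kept direction and side of the threshold, 45 moved further, 3 changed direction and 2 no longer passed. At 17590599 to 26177587 reads per library, 412 holds 51 and 42 reads in 412KD and scramble, and the interval of 0.730 to 1.73 for their ratio covers counting error only. With a log2 fold change of −0.03 and an SE of 0.41 between libraries for DM412, a fall of 412 below that interval is not excluded either.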

Other observations

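The tests of AT-rich reads and of neighbouring genes and the classes of repeat features were chosen after the result was seen.

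Of the telomeric retrotransposons, which maintain fly chromosome ends, the 2 TART features, which can share reads, were low in the libraries labelled RooKD. TART_B1 (−2.63 ± 0.22) passed edgeR and TART (−1.68 ± 0.32) passed DESeq2, while HETA (−0.39 ± 0.28) and TAHRE (−0.01 ± 0.33) passed neither, and TAHRE was above 0 without RooKD replicate 1 (0.27) or scramble replicate 3 (0.10). The 4 features had a median log2 fold change of −1.03 (camera p = 0.00035, and p = 0.0263 with an estimated correlation), but the class was made after TART_B1 had been called, so these p largely restate TART and TART_B1. In the libraries labelled 412KD the 4 features had a median of −0.58 with 3 below 0 (camera p = 0.096, and p = 0.183 with an estimated correlation). There TART_B1 (−1.12 ± 0.27) and HETA (−1.14 ± 0.23) passed DESeq2 (adjusted p = 0.00699 and 0.00278) but not edgeR (adjusted p = 0.245 and 0.167). With 1 library left out in turn, the edgeR adjusted p ranged from 0.0505 to 0.723 for TART_B1 and from 0.0944 to 0.597 for HETA. The other classes tested in 412KD were DNA transposons (6 of 10 above 0, median 0.45, camera p = 0.00497, and p = 0.0579 with an estimated correlation), LINE (p = 0.101 and 0.412) and LTR features (p = 0.204 and 0.651). In RooKD these classes, in the same order, had camera p = 0.182, 0.833 and 0.966, and p = 0.445, 0.880 and 0.973 with an estimated correlation. No p of a class is adjusted for the number of classes.

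Hr51 (2R, 15331325 to 15339384) and its neighbours CG8160 (15327143 to 15328271) and unc-5, a netrin receptor gene (15340472 to 15368300), were lower in both labelled groups by DESeq2. The log2 fold changes were −3.33, −3.14 and −2.05 in 412KD and −3.69, −3.28 and −1.51 in RooKD, where Hr51 alone passed edgeR. On 3L, spd-2 (16591207 to 16595014), CR18217 (16600448 to 16602723) and Abl (16615866 to 16647882) were all higher in 412KD by edgeR without 412KD replicate 3, and with all libraries CR18217 alone passed.

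Such runs of neighbours may come from local differences of the genome between the fly stocks, a hypothesis. Among the 300 genes with the smallest p, 38 same-direction neighbours lay within 20 kb in 412KD against scramble, above the 9 other splits of the 6 libraries (19 to 32, median 28). In RooKD against scramble there were 27, within the other splits (16 to 34, median 21), so the test does not decide there. In 412KD it does not decide either, since 10 splits are too few for a share under 0.05. Neighbours that change together through a hairpin or a tissue difference would also raise the count.

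Low-complexity AT-rich reads varied with the mitochondrially encoded genes across the 9 libraries. The log2 CPM of AT-rich reads and the mean log2 CPM of these genes had a Pearson r of 0.816 (exact permutation p = 0.00908, adjusted p = 0.00908, n = 9) and a Spearman rho of 0.867 (exact permutation p = 0.00451, adjusted p = 0.00902), adjusted over these 2 relations. Without RooKD replicate 3 and 412KD replicate 3, r was 0.892. The reads may come from the A+T-rich part of the mitochondrial genome, a hypothesis. Both measures were high in the libraries labelled 412KD, so the relation also holds the difference between the groups. With both measures centred on their group means, a relation added later, the Pearson r was 0.755 (exact permutation within groups p = 0.0417, adjusted p = 0.0417 over all 3 relations, n = 9), and 0.724 to 0.947 with 1 library left out in turn.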
